A study of Drosophila melanogaster with 2 samples.

How the data were processed

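The data came from 2 biological replicates of ChIP-seq on whole *Drosophila melanogaster* embryos of 0 to 16 h and both sexes, from a line expressing Kah with a C-terminal GFP tag. Per the labels, chromatin was broken by sonication to 200 to 800 bp and the genome build was dm6. Replicate numbers were taken from the labels, which call the replicates biological. Both belong to 1 group, so no groups were compared.

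The files used were peak lists in narrowPeak format, with 1 candidate list per replicate, 1 candidate list made by the authors from the alignments of both replicates together, and the list of peaks that passed the authors' IDR threshold. Per the deposited file listing, each candidate list was made from the replicate's alignment and 1 control alignment shared by both replicates, and the IDR list from the 3 candidate lists. The signal of each peak is the value the authors' peak caller gave it. Its scaling is not stated, so ranks, ratios, log2 differences and sums of signal hold only on the caller's own scale, and a ratio between replicates also reflects their unknown depths. The −log10 q in the deposited lists is capped at a top value in each list, and all 4105 IDR peaks stood at that value, so it was not used to rank peaks. The aligner, peak caller, their versions and filters are not given in the sources used here. The authors called the pooled list on both replicates together and chose IDR peaks by agreement between them. The recurrence of IDR peaks in the replicates and the correlation of their signals are therefore not independent tests of the peaks. The signal tracks were not used here. Read depth per library is unknown.

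Coordinates are 1-based in dm6. Sequence came from the Release 6 assembly, on which 0 peaks ran beyond a chromosome end, and genes from Ensembl release 115. A promoter was the 500 bp to either side of the TSS of any protein-coding transcript. A summit was assigned to a 5' UTR, coding exon, 3' UTR, exon of a non-coding transcript, intron or intergenic sequence, in that order of priority. Summits matched when they were within 100 bp. The chance expectation of matches came from 100 circular shifts of the replicate summits. Background candidates for IDR peaks were the 24795 pooled candidates more than 500 bp from an IDR summit. Motifs and 6-mers (strand-merged) were counted as present or absent within 50 bp of the summit on either strand.

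Shares were compared with two-sided Fisher's exact tests. Odds ratios have Wald 95% intervals, with 0.5 added to each cell only where a cell was 0. Benjamini-Hochberg adjustment ran over all 20 motifs, all 6-mers, all tested gene lists, 6 chromosomes or 6 annotation classes, as named, at a threshold of 0.05. Correlations and the signal difference used 100000 permutations, and the interval of the difference 2000 bootstrap draws. Peaks and genes are not independent replicates, so these tests describe how the listed regions differ and not how they would differ in new embryos. For gene lists, the background was the 7461 protein-coding genes with a pooled candidate within 500 bp of a TSS, since only these could have had an IDR promoter peak.

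The groups, tests, 20 motifs, 25 gene lists and the alternatives to be tried were fixed before the data were examined. Later, 4 older gene symbols were replaced by current ones, 2 older symbols of genes already listed were merged with them, and 1 listed symbol with no gene was dropped, all before any list was tested. After a first look at the list results, Cp110, Cp190 and Cpr, which encode no chorion or cuticle proteins, were removed from the lists whose name pattern had caught them. The lists past the threshold were the ribosomal protein and steroid response genes both before and after this removal. Peaks and genes were named by a rule fixed in advance, which took the 20 strongest IDR peaks with their nearest TSS, every Snail-family gene, Kah itself, up to 4 members of each list with the strongest IDR promoter peak, every listed motif and the 10 6-mers of smallest p. Genes at a shared peak were named together. The steroid response genes with a peak beyond those 4, the genes named at runs of neighbouring peaks, the 6-mers that were less frequent and the words of 7 bases were chosen after their values were seen. A list of other highly transcribed genes (33 found in the annotation, 32 tested) was added for the closing section, after the result of the ribosomal protein genes was seen and before its own.

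The tests were tried on simulated data. With 6-mers planted in windows of non-IDR candidates (4105 windows), 10 of 10 planted in 4% of windows and 10 of 10 planted in 2% were recovered. With nothing planted, 0 were called, in a random split of those windows that cannot show differences in base composition. Beside the planted words, 2 others sharing fewer than 5 bases with any of them were called. For gene lists drawn from the 7461 background genes, with the share of genes with a peak raised to 75%, 5 of 5 lists of 20 genes and 5 of 5 of 80 genes were called, and 0 of 5 unchanged lists of either size. Lists of fewer than 20 genes, smaller rises and lowered shares were not simulated. Alternatives covered the stricter 2052 IDR peaks of highest signal, each replicate alone (its 4105 strongest candidates in place of the IDR peaks), other matching distances, promoter windows and summit windows, other background candidates and sequences, other background genes and the chromosomes used. Analyses ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures in matplotlib 3.10.9.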

Results

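Binding of Kahuli (Kah, also CG17181), a zinc finger protein of the Snail family, was measured by ChIP-seq in whole embryos of the fruit fly *Drosophila melanogaster*. ChIP-seq recovers DNA fragments bound to a protein with an antibody and sequences them. The embryos were 0 to 16 h old, of both sexes, and came from a transgenic line in which Kah carried a C-terminal green fluorescent protein (GFP) tag. The design held 1 group with 2 biological replicates and no second condition, so the comparisons were between the replicates and between regions of the genome. The labels were in conflict on 1 point. The assay is given as transcription factor ChIP-seq with kah as the antibody target, while the free-text description of both libraries speaks of an input control. The values were analysed as ChIP-seq peaks, as the file listing describes them.

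Each replicate had a list of 30000 candidate peaks, and a further 30000 candidates had been called on both replicates together. From these the authors kept 4105 summits in 4048 intervals by the irreproducible discovery rate (IDR), a measure of how alike replicates rank their peaks. These are called IDR peaks here. They were exactly the 4105 candidates of highest signal in the pooled list, so that a comparison of IDR peaks with other candidates is a comparison of high with low signal. The lowest IDR peak had a signal of 149.7 and the highest remaining candidate 149.6. Median signal was 30.4 in replicate 1, 33.9 in replicate 2, 58.1 in the pooled list and 233 in the IDR list. Read depth is unknown, because the lists hold no read counts. Shares of peaks are given with exact Clopper-Pearson 95% intervals, which cover counting error only.

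The replicates found largely the same places, though less often for IDR peaks of lower signal. Of the 4105 IDR summits, 70.2% (68.8 to 71.6%) had a summit within 100 bp among the 4105 highest-signal candidates of both replicates. Replicate 1 held 84.4% of them and replicate 2 held 83.9%, while 1.95% were in neither. When the replicate summits were shifted along each chromosome at random 100 times, 0.629% of IDR summits were matched in replicate 1 and 0.624% in replicate 2. Signals were also ordered alike. Across the 3902 IDR peaks with a candidate in both full lists, Pearson's r of log2 signal was 0.779 and Spearman's rho was 0.667, each with a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give, and the same after adjustment over both. These correlations run across peaks, which are not independent replicates and were chosen by agreement between the same 2 libraries. The log2 ratio of replicate 2 to replicate 1 had an SD of 0.57 over peaks, which is 1.49-fold, and 74.5% of peaks lay within 1.5-fold of the median ratio.

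**Figure D1:**
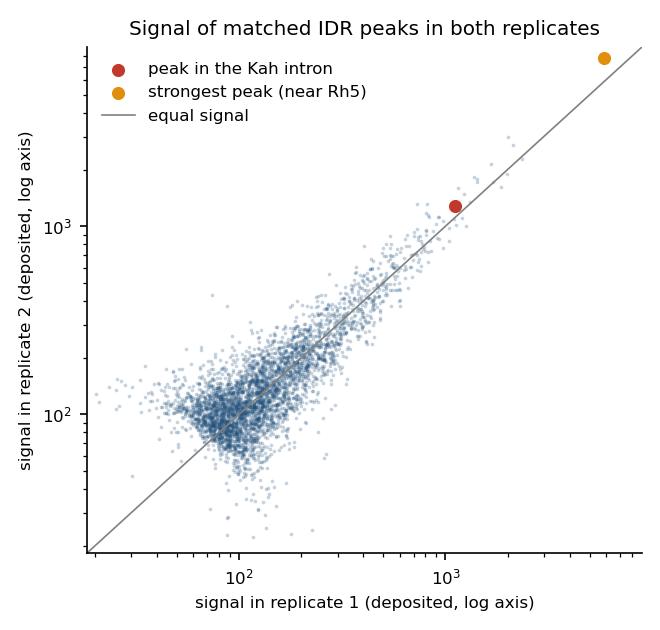
Signal of the 3902 matched IDR peaks in replicate 1 (x axis) and replicate 2 (y axis), as deposited and without a unit, on log axes, with 1 point per peak and a line of equal signal. The peak in the Kah intron (1110 and 1279) and the strongest peak, near Rh5 (5904 and 7806), lie close to the line.

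The strongest peak of the genome lay on chromosome 2L at 12010438 to 12012715 (dm6), with its summit at 12012362. Its signal was 13674, against 5904 in replicate 1 and 7806 in replicate 2, and was 2.72-fold that of the next peak. The summit was intergenic, between Rh5, which encodes a light-sensing rhodopsin (FBgn0014019, 12008153 to 12009832), and the non-coding gene lncRNA:CR44588 (12013528 to 12013899). The nearest protein-coding transcription start site (TSS) was that of Rh5, at 3984 bp. The 31 bp centred on the summit read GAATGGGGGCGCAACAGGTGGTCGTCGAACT and hold CAGGTG, the core site of Snail-family proteins, starting 1 bp before the summit. Another of the 20 strongest peaks lay on the other side of Rh5, at 12006911 to 12007937, with its summit 604 bp upstream of the gene and a signal of 3821.

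Of the 20 strongest IDR peaks, 14 lay within 500 bp of a protein-coding TSS and all 20 had a candidate within 100 bp in both replicates. Peaks inside introns included those of Mob2, a regulator of protein kinases (chromosome 3L, summit 11553495, signal 5020), and Mef2, a transcription factor of muscle differentiation (2R, summit 9955311, signal 3222, 3547 bp from the nearest TSS). A shared promoter peak of Vti1b and Vha100-2, a membrane fusion protein and a proton pump subunit, reached 3898 on 3R at 18399654. Its 31 bp read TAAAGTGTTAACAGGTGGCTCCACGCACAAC. Further promoter peaks, with their signals in brackets, belonged to CG4297 (4792), the mitochondrial enzyme gene Echs1 (4632), CG9117 with CG31643 (3501), CG8089 with CG7544 (3420), DEF8 (3206), RhoGAP18B (3162), the translation-control kinase gene PEK (2729), CG14511 (2706) and the sugar transporter gene Ugalt (2649). The same held for Oseg6 with Rep (2302), CG14100 (2258) and the ubiquitin ligase gene Nedd4 (2118). Summits farther from a TSS were those in a CG11050 intron (2201, at 1035 bp) and between genes 7632 bp from the TSS of RYBP (2117). CAGGTG lay within 50 bp of the summit in 7 of the 20.

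Kah itself carried 1 of the 20 strongest peaks. The gene (FBgn0035144, chromosome 3L, 582824 to 589274, minus strand) had its main summit in an intron at 586781, with a signal of 2396 (1110 in replicate 1 and 1279 in replicate 2). The surrounding 31 bp were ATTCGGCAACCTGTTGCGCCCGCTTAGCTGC, and no CAGGTG lay within 50 bp. Within 10000 bp of the gene there were 6 IDR peaks, 3 of them inside it. A peak 424 bp from its TSS, at 589698, had a signal of 1455, and another at 592412, between Kah and MED14, had 1944. The strongest of these summits differed between replicates by 0.24 SD of the log2 ratio over all matched peaks, after centring, and the other 5 by 0.619 to 1.70 SD in either direction. Among the other Snail-family genes, CG12605 had 2 IDR peaks within 10000 bp (highest signal 337, in an intron at 3L 3961218, with CAGGTG). The neuroblast and imaginal cell factor esg had 1 (signal 219, at 2L 15333706, 160 bp upstream of the annotated gene). The Snail gene sna itself, wor and scrt had 0 IDR peaks within that distance, although the same regions held 3, 9 and 10 candidates of lower signal.

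**Figure D2:**
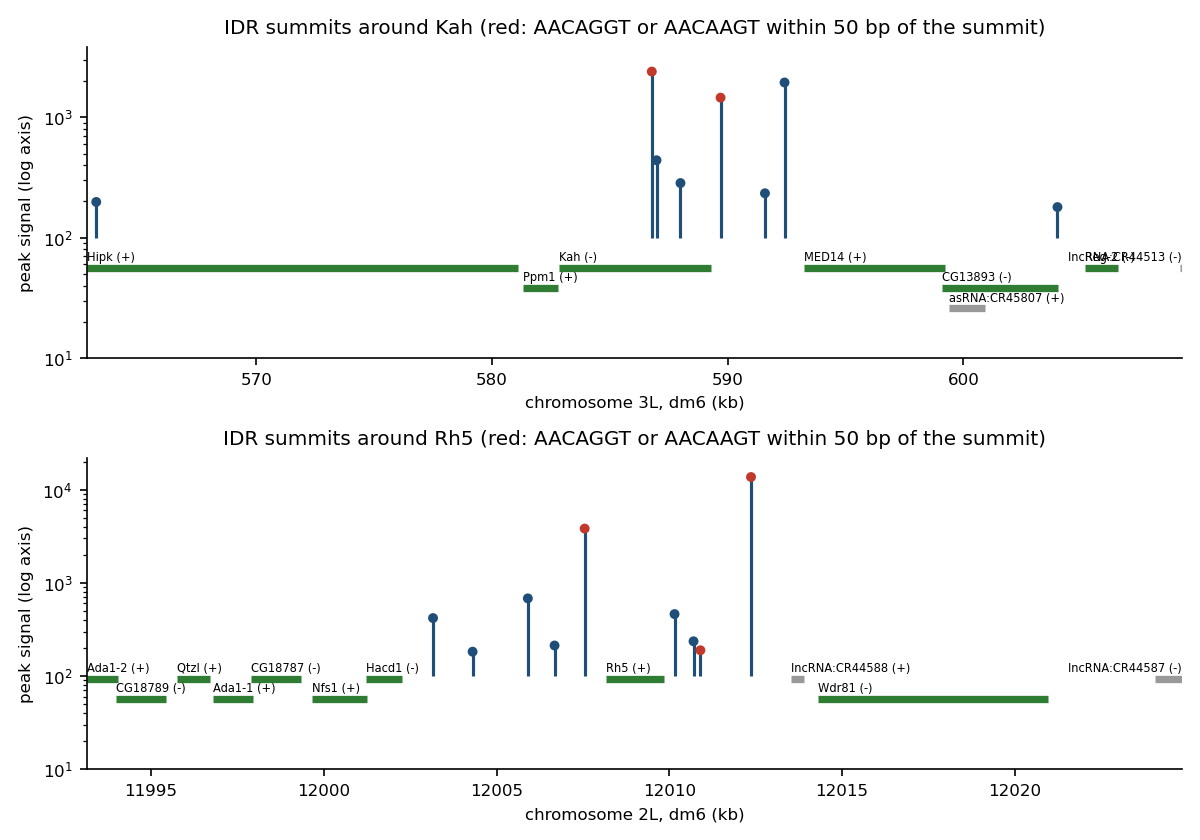
IDR summits around Kah (top, chromosome 3L) and Rh5 (bottom, chromosome 2L) in dm6 coordinates in kb, with stems from 100 to the deposited signal on a log axis, red heads at summits with AACAGGT or AACAAGT within 50 bp, and bars for protein-coding (green) and non-coding (grey) genes. The highest stems are the Kah intron peak (2396) and the intergenic peak downstream of Rh5 (13674).

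IDR peaks lay at promoters more often than other candidates did. Of the IDR summits, 50.5% (48.9 to 52.0%) lay within 500 bp of a protein-coding TSS, against 26.1% of the 24795 candidates that lay more than 500 bp from any IDR summit (odds ratio 2.88, 95% interval 2.69 to 3.08, two-sided Fisher's exact p = 4.82e-204). The median distance to a protein-coding TSS was 478 bp for IDR summits and 2003 bp for other candidates, and 2375 protein-coding genes had an IDR promoter peak. By annotation, 16.3% of IDR summits lay in 5' UTRs against 9.90% of other candidates, 2.73% against 5.85% in coding exons and 0.877% against 3.21% in 3' UTRs. Introns held 47.6% against 50.2% and intergenic sequence 29.7% against 28.1% (Benjamini-Hochberg adjusted Fisher's p = 3.13e-30, 2.26e-18, 1.43e-20, 0.00217 and 0.0476, in that order). Exons of non-coding transcripts did not differ detectably (2.90% against 2.69%, adjusted p = 0.468 by the same exact test). Of the IDR summits, 15.1% were more than 5000 bp from any protein-coding TSS. The same share was not computed for other candidates. Against only the 4105 remaining candidates of highest signal, 41.8% of which were at promoters, the odds ratio fell to 1.42 (1.30 to 1.55, exact p = 4.44e-15). By signal rank in the pooled list, the promoter share was 59.9% in ranks 1 to 1000 and 46.6% in 3001 to 4000. Past the IDR threshold it was 44.8% in 5001 to 6000 and 16.6% in 28001 to 29000. Whether this gradient reflects binding of Kah or non-specific recovery of promoters was not tested.

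The Snail-family site CAGGTG was more frequent at IDR summits than at other candidates. It lay within 50 bp of 9.87% of IDR summits (405 of 4105, 8.97 to 10.8%) and of 5.36% of the others (odds ratio 1.93, 1.72 to 2.17, Fisher's exact test adjusted over 20 motifs p = 1.22e-24). Its density was highest at the summit itself, with 1.47 sites per kb in the 20 bp before IDR summits against 0.647 in other candidates. By the base before the site, ACAGGTG had an odds ratio of 2.45 (2.08 to 2.88, exact test adjusted over 8 words p = 3.90e-23) and GCAGGTG 1.61 (1.30 to 1.99, 4.91e-05), while CCAGGTG (1.41) and TCAGGTG (1.37) did not pass the test (0.0746 for both). By the base after it, CAGGTGT (2.64) and CAGGTGG (2.39) were more frequent at IDR summits (exact adjusted p = 9.47e-17 and 2.39e-21), and CAGGTGA (0.868) and CAGGTGC (1.1) did not pass (0.522 for both). Differences between these words were not tested.

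Other motifs of embryonic regulators had smaller odds ratios than CAGGTG. More frequent at IDR summits were AGGTGG, part of the CTCF site and overlapping CAGGTGG (7.82% against 4.88%, odds ratio 1.65, exact test with adjusted p = 8.37e-13), the Mef2-like core TATTTA (23.9% against 17.2%, 1.51, 2.21e-22) and the GAGA factor site GAGAGA (7.87% against 5.45%, 1.48, 1.88e-08). The same was true of the Tinman site CACTTG (10.5% against 8.09%, 1.33, 2.99e-06), CAGGTA of the early activator Zelda (2.87% against 2.19%, 1.32, 0.0176) and the homeodomain core TAATTA (8.28% against 6.41%, 1.32, 5.07e-05). CACTTG, which is CAAGTG on the other strand, and CAGGTA overlap the leading 6-mers ACAAGT and ACAGGT given below. The joined words ACAAGTG (5.55% against 2.34%) and ACAGGTA (1.53% against 0.807%) were also more frequent at IDR summits. Whether CACTTG or CAGGTA was raised apart from these words was not tested. These comparisons did not match candidates on GC content or promoter position. Less frequent were GGGGGG (odds ratio 0.674, exact test with adjusted p = 0.00227), the shuffled control GTGGAC (0.703, 0.00789) and the Sox site ACAATG (0.840, 0.0391). No difference was detected for the E-boxes CAGCTG (1.09), CATATG (1.2), CACATG (0.888) and CACGTG (1.17), the control GACGTG (0.927), the DREF core ATCGAT (1.11), the repeat ACACAC (1.01), the Grainyhead core AACCGG (0.944), the M1BP core GTCACA (1.13) and the GATA site AGATAA (1.02), with exact-test adjusted p from 0.199 to 0.862.

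**Figure D3:**
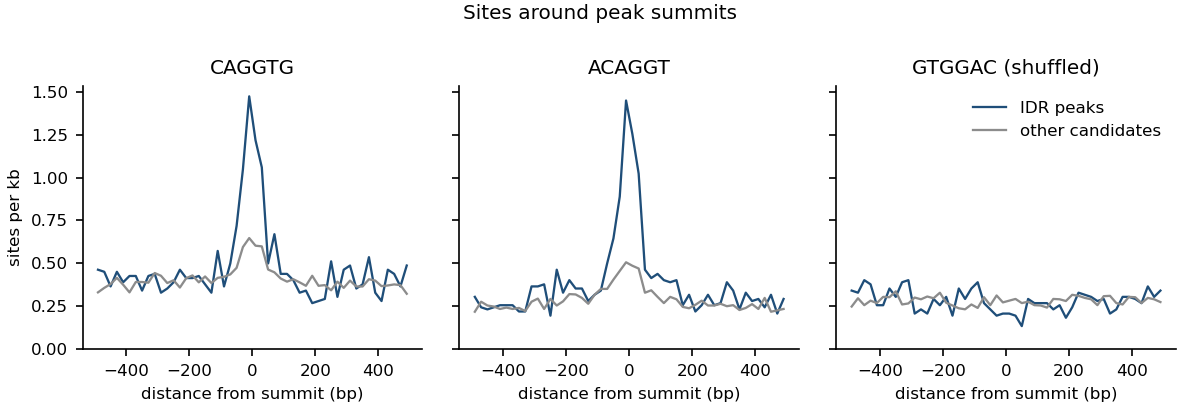
Density of CAGGTG, ACAGGT and the shuffled control GTGGAC (sites per kb on either strand, y axis) by distance from the summit in bp (x axis, steps of 20 bp) for the 4105 IDR peaks (blue) and 24795 other candidates (grey). CAGGTG reaches 1.47 sites per kb beside IDR summits and ACAGGT 1.45, while the control has 0.207 there.

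With no motif given in advance, the 6-mer that led was ACAGGT, which overlaps the Snail site. ACAGGT lay within 50 bp of 9.48% of IDR summits and 4.32% of other candidates (odds ratio 2.32, 2.05 to 2.61, exact test with adjusted p = 3.81e-34). AACAGG followed (9.99% against 4.81%, odds ratio 2.20), then CACCTG, the reverse complement of CAGGTG (1.93), and ACAAGT (10.8% against 6.28%, 1.81) and AACAAG (12.1% against 7.57%, 1.68). The remaining members of the 10 leading words were the AT-rich ATTTAA (1.56), TAAATA (1.51), TTAAAA (1.52), TTTAAA (1.63) and ATTTTA (1.48). TAAATA is the reverse complement of the Mef2-like core TATTTA above, so the 2 are the same result. In all, 215 of the 6-mers were more frequent at IDR summits and 334 less frequent at an adjusted p under 0.05, with GGAGGA (odds ratio 0.425), CCTCCA (0.485), CAGGAC (0.353), CCAGGA (0.429) and GCAGGA (0.512) leading the latter. When candidates were matched on GC content and promoter position, 36 were more and 10 less frequent, where ACAGGT still led (2.72) and ATTTAA no longer passed (1.16, exact test with adjusted p = 0.181). Against the strongest remaining candidates 23 were more frequent, led by AACAGG, and 7 less frequent, and within 25 bp of the summit the numbers were 139, led by ACAGGT, and 114.

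IDR peaks with CAGGTG were slightly stronger than those without it. Their median signal was 262 (405 peaks) against 230 (3700 peaks), a difference of 0.19 in median log2 signal (bootstrap 95% interval 0.08 to 0.34, two-sided permutation p = 0.00012). At promoters the difference was 0.27 (permutation p = 0.00032) and away from them 0.11 (p = 0.037); whether these differ was not tested. Along the whole pooled list, CAGGTG was present in 13.5% of the 1000 candidates of highest signal and in 9.80%, 8.80% and 7.40% of the next 3 groups of 1000.

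**Figure D4:**
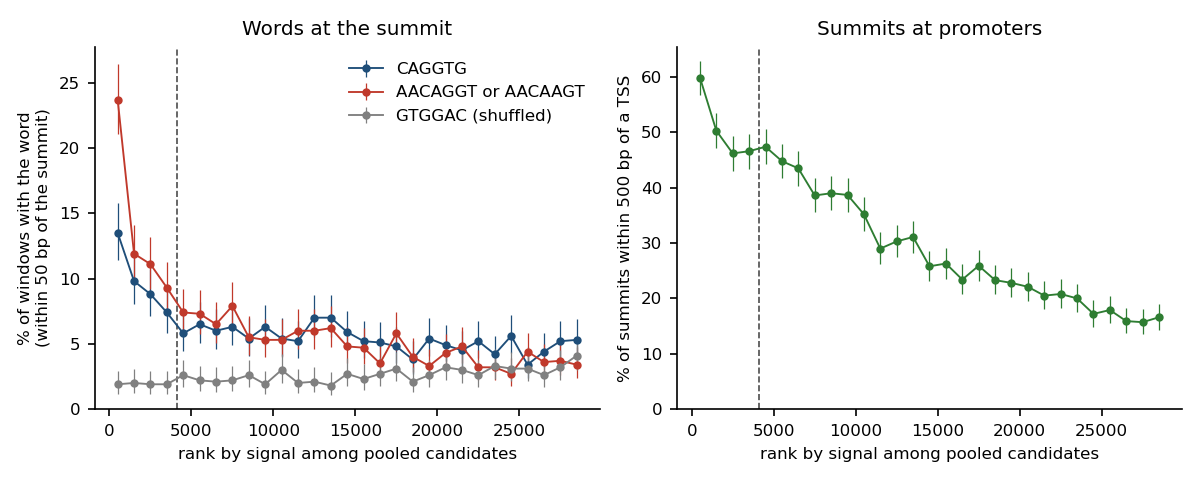
Left, percent of candidates with CAGGTG (blue), AACAGGT or AACAAGT (red) or the shuffled control GTGGAC (grey) within 50 bp of the summit, and right, percent of summits within 500 bp of a TSS (green), in groups of 1000 pooled candidates ordered by signal (x axis, rank), with exact 95% intervals and a dashed line at the last IDR peak. The top group has 13.5% with CAGGTG, 23.7% with AACAGGT or AACAAGT (words chosen after the 6-mers were seen), 1.9% with the control and 59.9% at promoters.

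Ribosomal protein genes carried promoter peaks far more often than other genes. Of the 7461 protein-coding genes with any candidate within 500 bp of a TSS, 2375 (31.8%) had an IDR peak there. Among ribosomal protein genes it was 69 of 88 (78.4%, 68.4 to 86.5%), with an odds ratio of 7.98 (4.79 to 13.3, Fisher's exact test adjusted over 23 lists p = 4.79e-18). The highest signals were at RpL34b with CG8132 (837, but 73.4 in replicate 1 and 429 in replicate 2), RpS27 with Nup37 (718), RpS16 with CG4294 (659) and RpL24 (652). Only 1 of the 71 peaks at these promoters held CAGGTG, against 200 of 2001 other promoter IDR peaks (odds ratio 0.129, Fisher's exact p = 0.0123).

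Genes of the steroid hormone response were the other list with more promoter peaks than expected from its candidates. IDR peaks lay at 8 of 10 (odds ratio 8.59, 1.82 to 40.5, exact test with adjusted p = 0.0279). These were the ecdysone receptor gene EcR, its partner usp, and the nuclear receptor genes Eip75B, Hr3, Hr4, Hr39, Hr78 and ftz-f1, led by Hr78 (signal 1099, with CAGGTG), Eip75B (371), Hr4 (292) and usp with CG4313 (215). The call ended under 3 alternatives. By the same exact test it was 6 of 11 without replicate 2 (odds ratio 2.42, adjusted p = 0.474), among the 2052 strongest IDR peaks 3 of 10 (adjusted p = 0.719), and with canonical TSSs alone 4 of 9 (adjusted p = 0.688).

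Signalling and tissue lists did not pass the test. IDR promoter peaks were found at 8 of 13 genes of the Dpp (BMP) pathway (odds ratio 3.43, exact test with adjusted p = 0.190), with the highest signals at tup (520, with CAGGTG), Med with CycG (487), shn (385) and the receptor gene tkv (341). This list passed with promoters of 1000 bp to either side (11 of 14, odds ratio 7.28, exact test with adjusted p = 0.00882). IDR promoter peaks lay at 9 of 18 Wnt pathway genes (pan 636, sgg 630, fz 421, nkd 360), 6 of 12 genes of the EGFR and FGF pathways (spi 464, pnt 400, bnl 363, aop 210) and 7 of 21 Notch pathway genes (E(spl)m7-HLH 808, mib1 465, E(spl)m3-HLH 400, gro 386). Hedgehog pathway genes had them at 4 of 10 (rdx 279, ptc 276, ci 203, ihog 150.4). Muscle structural genes gave 12 of 26 (Zasp52 803, up 768, Tm2 356, Msp300 282), glial genes 4 of 7 (moody 585, pnt 400, nrv2 247, ttk 158) and mesoderm regulators 5 of 19 (tin 343, stumps 247, Doc2 244, Doc3 186). Exact-test adjusted p ranged from 0.320 to 1 for these lists other than Dpp.

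Neural and patterning lists did not differ detectably from other genes. IDR peaks lay at 4 of 20 neuroblast genes (numb 393, pros 258, esg 219, brat 181), 3 of 14 genes of neuronal differentiation (elav 804, Fas2 254, jeb 228), 3 of 10 tracheal and salivary gland genes (fkh 440, trh 385, bnl 363) and 1 of 4 genes of hemocytes and fat body (Pvr 512). Snail-family genes gave 2 of 6 (Kah 1455, esg 219), gap and pair-rule genes 1 of 12 (hry 186) and Hox genes 0 of 6 (exact upper 95% bound 45.9%). Exact-test adjusted p was between 0.320 and 1.

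General cellular lists and late or adult gene families did not pass either, though 5 of them passed as lower under other settings. Polycomb and Trithorax genes had IDR promoter peaks at 7 of 15 (ph-p 1544, brm with Arl1 649, E(z) with Cnep1r2 445, Su(z)2 401, exact test with adjusted p = 0.438) and cell cycle genes at 5 of 16 (dap 327, E2f1 261, dup with SRPK 261, fzr 165, adjusted p = 1). Mitochondrial ribosome genes had them at 12 of 59 (mRpS10 with Art3 1869, mRpL41 1738, mRpS23 with CenG1A 1445, mRpL3 with Graf 912) and proteasome genes at 3 of 22 (Rpt3R with Alg12 724, Prosbeta5 with dgo 318, Prosalpha6 with Npc1a 151), each with an exact-test adjusted p of 0.230. Chemosensory receptor genes gave 0 of 9 (exact upper bound 33.6%, adjusted p = 0.230) and cuticle protein genes 0 of 13 (upper bound 24.7%, exact-test adjusted p = 0.100). Cuticle genes passed as lower without replicate 1 (0 of 15, exact-test adjusted p = 0.0335) and with promoters of 1000 bp to either side (2 of 27, 0.0214). With each candidate given to its nearest TSS up to 10000 bp away, 4 lists passed as lower, namely proteasome (0 of 17), mitochondrial ribosome (4 of 40), chemosensory receptor (5 of 44) and cuticle protein genes (2 of 29), each with an exact-test adjusted p of 0.00891. Against all protein-coding genes, chemosensory receptor (0 of 179), cuticle protein (0 of 93) and histone genes (0 of 111) passed as lower (exact-test adjusted p = 6.60e-14, 2.51e-07 and 1.61e-08). Only 9 of these chemosensory receptor genes, 13 of the cuticle protein genes and no histone gene had a candidate at a TSS. The rest could not have had an IDR peak there, so this background largely fixed the outcome, and for histone genes wholly. Chorion and vitelline genes and histone genes had no member among the 7461 tested genes. Genes are not independent replicates, and the number of lists with more peaks was 6 with the nearest TSS up to 10000 bp away (adding Dpp, Notch, muscle and Polycomb and Trithorax) and 5 against all protein-coding genes (adding Dpp, Wnt and muscle).

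**Figure D5:**
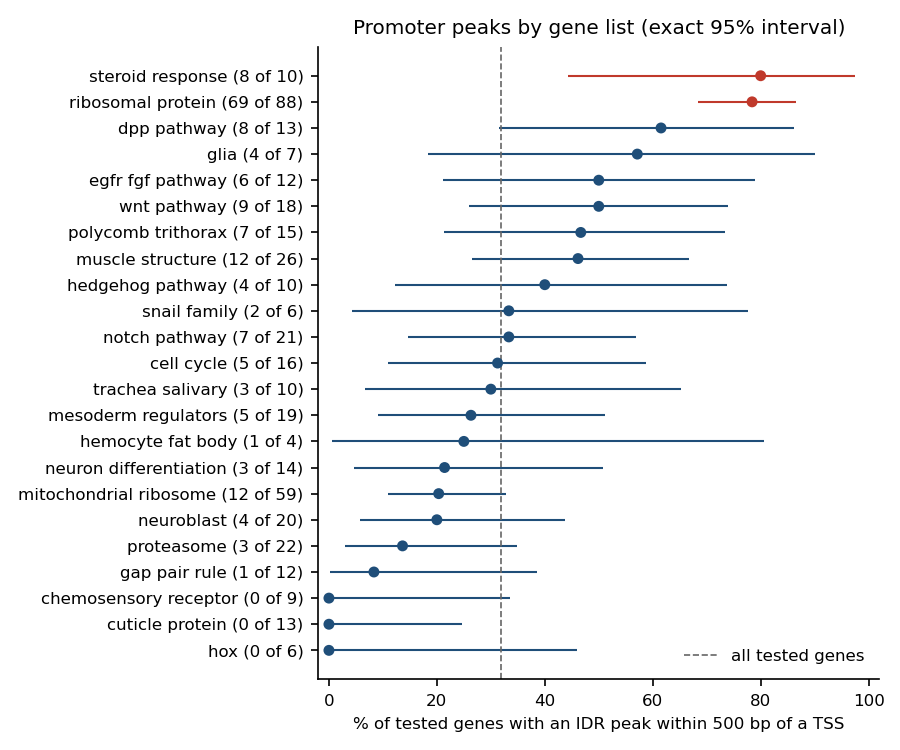
Percent of tested genes with an IDR peak within 500 bp of a TSS (x axis) for each of 23 gene lists, with exact 95% intervals, red for an adjusted p under 0.05 and a dashed line at the 31.8% of all tested genes. Steroid response genes (8 of 10) and ribosomal protein genes (78.4%) stand to the right.

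IDR peaks were spread over the large chromosome arms and sparse on chromosome 4. The small, largely heterochromatic chromosome 4 held 16 IDR peaks, or 11.9 per Mb and 0.390% of the total, against 0.968% of other candidates (odds ratio 0.40, 0.241 to 0.665, Fisher's exact test adjusted over 6 chromosomes p = 5.72e-04). IDR peaks per Mb were 33.8 on 2L, 31.2 on 2R, 31.6 on 3L, 30.3 on 3R and 27.4 on X. Per 100 protein-coding genes the gap was smaller, with 20 IDR peaks on chromosome 4 and 27.7 (2R) to 32.4 (3L) on the others. The X share was 15.7% of IDR peaks and 16.7% of other candidates, with no detectable difference (odds ratio 0.928, 0.848 to 1.02, exact p = 0.108, adjusted p = 0.216). It depended on the replicate, with an odds ratio of 0.876 (exact p = 0.00460) without replicate 1 and 1.01 (p = 0.908) without replicate 2. The other arms did not pass the test either (adjusted p from 0.114 to 0.633).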

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

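The alternatives of canonical TSSs and of CAGGTG only at, or only away from, promoters were chosen after seeing the data. Across 58 alternatives of 8 results, 43 kept the direction and the side of the threshold or, for numbers of 6-mers and gene lists, stayed within 1.5-fold. Of the rest, 1 passed the threshold that the reported value missed and 1 changed direction. The other 13 moved beyond that fold or, for the share found in both replicates, outside its interval. Direction and call were kept in every alternative run for promoters (odds ratio 1.42 to 3.45), CAGGTG at summits (1.65 to 2.57), the rank correlation (0.644 to 0.713) and the signal with CAGGTG (log2 difference 0.11 to 0.27). The share of IDR peaks found in both replicates was 95.5% for the 2052 strongest peaks, 75.6% for summits within 250 bp, 62.4% within 50 bp, 75.6% for overlapping intervals and 95.1% against all candidates of each replicate; the last widens the lists searched and the distances widen or narrow the match, and for the strongest peaks the cause was not tested. The number of more frequent 6-mers was 139 within 25 bp of the summit, 36 against candidates matched on GC content and promoter position and 23 against the strongest non-IDR candidates; the matched and strongest sets hold fewer windows, and the share of the drop due to this was not tested. The number of gene lists with more promoter peaks was 1 for the 2052 strongest peaks, 6 for the nearest TSS up to 10000 bp, 5 against all protein-coding genes, 3 within 1000 bp, 1 for canonical TSSs and 1 to 2 without 1 replicate. Lists with fewer peaks, 0 as reported, were 4 for the nearest TSS, 3 against all protein-coding genes, 1 within 1000 bp and 1 without replicate 1. Against all protein-coding genes, most members of the 3 lists had no candidate at a TSS and so could not have a peak there. The cause in the other settings was not tested. The odds ratio on X ranged from 0.876 (without replicate 1) to 1.01 (without replicate 2), and the cause was not tested. Leaving out a replicate was not possible for the recurrence and the correlation, which need both. No paired analysis was possible because there is 1 group. Unknown read depth limits any statement on peaks below the IDR threshold.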

Other observations

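The words of 7 bases, the runs of neighbouring peaks, the non-coding genes, the words at ribosomal protein promoters and the tests of a single raised library, of the main Kah summit against the rest of the gene and of CAGGTG apart from AACAGGT were chosen after the results were seen. The leading 6-mers were most enriched with an A before them, though differences between the words were not tested. AACAGGT lay within 50 bp of 7.16% of IDR summits and 2.14% of other candidates (odds ratio 3.53, 3.04 to 4.08, Fisher's exact test adjusted over 16 words p = 4.76e-54), and AACAAGT of 6.97% and 2.74% (2.66, adjusted p = 2.99e-35). With C, G or T before ACAGGT the odds ratios were 1.07, 0.946 and 1.49 (exact test with adjusted p = 0.815, 0.901 and 0.0560), and before ACAAGT 1.24, 0.882 and 1.23, none passing. Either AACAGGT or AACAAGT was present at 13.9% of IDR summits against 4.84%, at 30.0% of the 500 strongest and at 14 of the 20 strongest, among them the peaks near Rh5 and in Kah. The odds ratio of 3.18 (2.86 to 3.54) was 3.26 at promoters, 3.16 away from them, 3.16 against candidates matched on GC content and promoter position and 5.18 against flanks of the same peaks. It was 3.44 without replicate 1 and 3.35 without replicate 2. Median signal was 305 with either word (572 peaks) and 226 without (3533 peaks).

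The Rh5 interval on 2L held the densest run of IDR summits, with 9 between 12003162 and 12012362 and a summed signal of 19874.5. These were not 9 separate peaks, as 12010699, 12010898 and 12012362 shared 1 interval, and 12012362 alone had a signal of 13674. Replicates 1 and 2 were uneven at 12006678 (226 and 24.4), 12010898 (26.7 and 150) and 12004307 (32.8 and 153), and less so at the others. Among the windows of 10000 bp that start at an IDR summit, 2076 held 1 and 11 held 7. Separate runs of 7 included those at cbt and ush on 2L (478857 to 485868) and at Raf and CG2865 on X (2293754 to 2302227). Of the 180 tRNA genes with a candidate within 500 bp of their start, 18 had an IDR peak, fewer than of protein-coding genes (odds ratio 0.238, 0.146 to 0.388, Fisher's exact test adjusted over 5 classes p = 2.40e-11). For other non-coding RNA genes it was 194 of 983 (0.527, exact test with adjusted p = 6.03e-15), and for snoRNA genes 20 of 60 (1.07, adjusted p = 0.782). Protein-coding genes were scored at the TSS of any transcript and non-coding genes at their start, which may raise the share of the former. Genes that share a candidate are not independent.

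Of the explanations weighed for peaks at ribosomal protein promoters, binding through CAGGTG is argued against, since the odds ratio of CAGGTG there against non-IDR promoter candidates was 0.276 (0.0382 to 1.99), below the 2.14 of other promoter IDR peaks. AACAGGT or AACAAGT was present in 1 of these 71 peaks and in 0 of 26 at other highly transcribed genes (upper 95% bound 13.2%), against 14.5% of remaining promoter IDR peaks (Fisher's exact p = 3.77e-04 and 0.0417). Non-specific recovery of highly transcribed promoters remains open as a candidate explanation, because 65.6% of other highly transcribed genes (21 of 32, such as those of elongation factors and actins) had a promoter IDR peak, above the remaining genes (odds ratio 4.22, exact p = 7.05e-05) and not detectably below ribosomal protein genes (odds ratio 0.526, 0.216 to 1.28, p = 0.161). The words that led at these promoters against other promoter peaks were CCGGAA (42.3% against 2.95%) and AAAGAA (64.8% against 12.7%), and no biological explanation was tested.

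CAGGTG at IDR summits was weighed against 3 explanations. Base composition and promoter content are argued against by an odds ratio of 2.44 (2.04 to 2.93) against matched candidates. A property of the wider region is argued against by 2.57 (2.21 to 2.99) against flanks of the same peaks. That CAGGTG is raised only as part of AACAGGT is argued against by 1.55 (1.34 to 1.80) in windows without AACAGGT or AACAAGT, although the reverse ratio, for those words in windows without CAGGTG, was larger at 3.06 (2.70 to 3.46). Other embryonic factors with like sites were not measured here, and no biological explanation was tested.

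The peaks at Kah may come from binding of the protein to its own gene or from extra copies of the region carried by the transgene. For the main summit, at 586781, a single raised library is argued against, as the replicates differed there by 0.24 SD of the log2 ratio over all matched peaks, after centring. This does not extend to every IDR peak within 20000 bp, since the centred ratio of replicate 2 to replicate 1 was 1.70 SD at 586981, 1.13 SD at 589698, 1.21 SD at 603991 and -1.19 SD at 591581, and 0.619 to 0.719 SD at the other 3. The SD was taken over matched IDR peaks of all signals, and the spread among strong peaks alone was not computed. Extra copies shared by the whole gene, as the only source of the main summit, could not be judged from its height. They would raise the gene by 1 factor. The main summit had 18.3-fold the median signal of the other 5 candidates inside Kah and 49.2-fold the lowest. However, it was picked as the highest of them. The bound of 2.21-fold, for 2 SD of the replicate ratio, is not the spread between candidates, which ran from 48.7 to 440 for the other 5. For the number of peaks nearby, extra copies and binding cannot be told apart, because the region within 20000 bp held 24 candidates, more than 91.4% of windows of the same length (median 9), between the bounds set in advance, and 8 IDR peaks, more than 98.7% of windows (median 1).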
